A study of Homo sapiens with 6 samples.

How the data were processed

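The data were log2 expression values of 6 arrays of U-2 OS cells, 3 expressing wt-progerin and 3 expressing S22A-progerin from a retroviral vector. Per the labels' protocols, cells were selected for 3 days in puromycin at 5 µg/ml, total RNA was extracted with Trizol 4 days after infection, and biotin-labelled targets for Affymetrix whole-transcript arrays were made with an Ambion kit. The deposited values are on the log2 scale and were made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, quantile normalizes the arrays and summarises the probes of each probe set. Versions and other settings of that step are not given in the sources used here. Each array was a column of its own, matched to its sample by the label, and groups came from the labels. Values ran from 1.27 to 14.0. No detection call or background signal was used here, so a low value cannot be told from absence, and folds from low values are compressed. The number of arrays limits the precision.

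Probes were named through the platform annotation. Of 53617 probes, here meaning probe sets, 16098 had 1 gene symbol, 0 had several and 37519 were not named here. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols and also gave the gene types and which genes neighbour each other. No genome build is named in the sources used here, so no coordinates are given. Of the 14884 genes tested, 779 had several probe sets, and the brightest by mean over the 6 arrays was used. In 4 genes the probe sets passed in opposite directions, and none of those genes is described, though 1 of them counts among the falls of the DNA repair list, which are 12, not 13, with probe sets averaged.

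Genes were tested with limma (version 3.58.1, R 4.3.3), lmFit and eBayes with default priors, 2 groups and no covariate, two-sided, with no filter on dim genes. P-values were adjusted by Benjamini-Hochberg over all tested genes and called at 0.05. Adjusted p-values of single genes are limma's throughout. Gene lists were tested with camera in limma at a preset correlation of 0.01, which compares a list's genes with all others, adjusted over the 27 lists tested. Camera with the correlation estimated per list and the rotation test fry were alternatives. The directional p-value of fry asks whether the genes of a list move, on balance, to 1 side, and its mixed p-value whether they change in either direction, and neither compares the list with other genes. Before the data were examined, 28 lists with 842 genes were fixed, of which 496 genes were measured. The list of replication-dependent histones had 0 named members and was not analysed here. Some genes stand in more than 1 list. Also fixed in advance were the design, the alternatives and the rule for named genes. That rule took LMNA, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, and up to 4 members of each list with the smallest p. A DNA repair gene that the rule takes is not reported here. Genes with LOC, LINC, MIR, SNOR, RNU or open reading frame symbols and pseudogenes were passed over among the rises and falls, though counted. List members named outside the rule were picked after their values were seen. Some were named because so few members moved that way or did not pass. Others lost their call in another fit, or were well known members not analysed.

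The code was tested on simulated arrays of 14884 genes with the real means and spreads of this comparison. At a true difference of 0.3 on the log2 scale it recovered 15 of 50 changed genes (30%), at 0.6 34 of 50 (68%), at 1 46 of 50 (92%) and at 2 49 of 50 (98%). Of 152 calls 8 were false. The list seeded with changes was called, and 0 lists were called without seeded changes. Noise was drawn independently for each gene, so this does not show how camera behaves where genes of a list vary together. A far smaller share of genes was changed than the 25.4% called in the data, so the recovery may differ there. Alternatives covered repeated quantile normalization, median centring, leaving out dim genes, averaging probe sets, testing every probe set, other variance priors, array weights, the replicate number as a fixed or random block, each array left out in turn, stricter thresholds, the estimated correlation and fry.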

Results

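Gene expression was measured on 6 whole-transcript arrays of U-2 OS, a human osteosarcoma line. The cells had been infected with a retrovirus carrying progerin and were collected 4 days later, after puromycin selection. Progerin is the truncated, permanently farnesylated form of lamin A that accumulates in Hutchinson-Gilford progeria. On 3 arrays the cells expressed progerin without the added change (wt-progerin). On the other 3 they expressed S22A-progerin, in which serine 22, a site phosphorylated when the lamina is taken apart at mitosis, is alanine. The comparison asks how expression differs when that residue cannot be phosphorylated. All differences are S22A-progerin minus wt-progerin on the log2 scale, with n = 3 arrays per group. No array of cells without progerin was analysed here, so the values do not tell which group departs from the starting line. Infection rate, cell number and cell cycle stage were not analysed here either.

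The 6 arrays had medians of 6.04 in each wt-progerin array and 6.05, 6.08 and 6.09 in the S22A-progerin arrays, over 53617 probes. Across genes, which are not independent replicates, arrays correlated at 0.996 to 0.997 within wt-progerin and 0.994 to 0.996 within S22A-progerin. Between the groups the correlation was 0.983 to 0.985. The first principal component held 69.1% of the variance and parted the groups. The second held 11.1%, and S22A-progerin replicate 3 scored -15.5 on it while replicates 1 and 2 of that group scored 6.51 and 9.29. Without that array 3601 genes passed the test. The mitosis list then had 52 lower members, the p53 list 17 higher and the NF-kB list 18 higher. Without wt-progerin replicate 3, AURKA, BUB3 and CENPN no longer passed in the mitosis list, nor did AEN, APAF1 and FBXO22 in the p53 list. The labels describe the replicates of each group as independent. The p-values measure the spread between these arrays.

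LMNA, the gene that encodes lamin A and progerin, was read at 8.17, 8.15 and 8.10 in wt-progerin and at 8.31, 8.26 and 8.29 in S22A-progerin. The means were 8.14 ± 0.036 and 8.29 ± 0.024 (SD, n = 3). The difference was 0.15 (SE 0.051, 95% interval 0.026 to 0.266), or 1.11-fold, and did not pass (adjusted p = 0.0796). The LMNA probe set was taken to read cellular and vector transcripts together, though its position was not checked here. It does not check the S22A change. With the arrays quantile normalized again the difference was 0.177 and passed, at adjusted p = 0.0356.

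**Figure D1:**
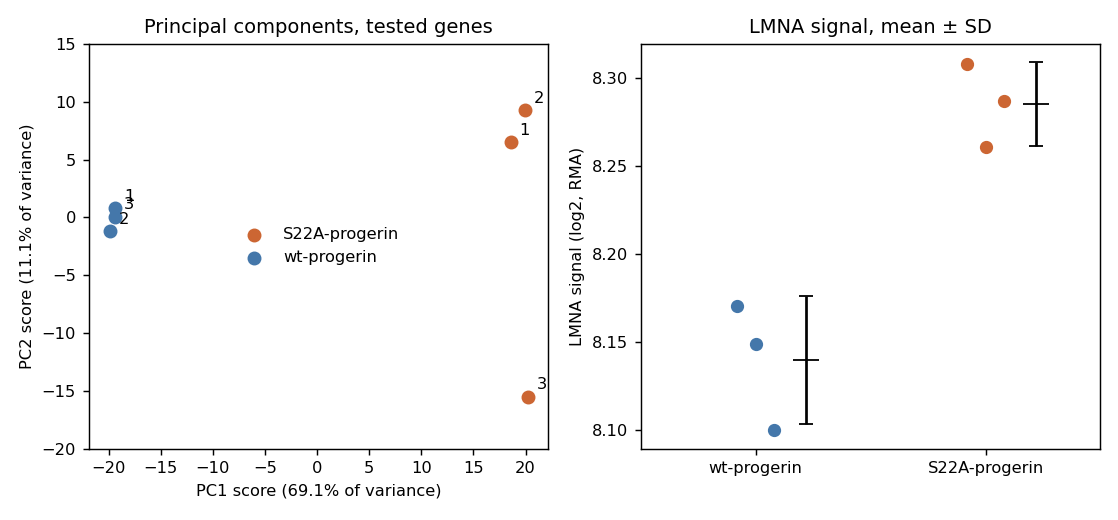
The left panel places the 6 arrays on the first 2 principal components of the tested genes, with the percent of variance on each axis and the replicate number beside each point. The right panel gives the log2 LMNA signal of each array with the mean and SD of each group (n = 3), 8.14 for wt-progerin and 8.29 for S22A-progerin.

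S22A-progerin cells had higher transcript levels of p53 and NF-kB target genes, and lower levels of genes for mitosis and chromosome condensation. GDF15, a stress-induced cytokine of the TGF-beta family, rose from 8.03 ± 0.046 to 11.58 ± 0.050 (SD, n = 3), 11.8-fold. CXCL8, a neutrophil chemokine, also rose 11.8-fold. All 53 measured genes of mitosis and cytokinesis fell, with a median of -0.68, a 1.60-fold difference. CXCL14, another chemokine, fell by 2.55 on the log2 scale. Of 14884 genes, 3777 (25.4%) passed at an adjusted p under 0.05, with 1601 higher and 2176 lower in S22A-progerin. Most differences were small, with a median size of 0.38 among the genes that passed. At a fold of at least 2, 152 genes were higher and 76 lower, and at a fold of at least 4, 28 were higher and 2 lower. In 6266 genes (42.1%) the values of the 2 groups did not overlap, where chance gives 10%. The median difference over all genes was close to 0.

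By the kind of gene, 1402 of 11916 protein-coding genes rose and 2000 fell. Of 1398 long noncoding RNA genes, 105 rose and 109 fell. By level, rises outnumbered falls in the lowest tertile of genes, at 333 against 176 of 4962. In the highest tertile of 4961 genes, 705 rose and 1268 fell.

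The largest rise was in ESM1, which encodes endocan, a secreted proteoglycan. Its mean went from 6.48 to 10.33, a difference of 3.85 (SE 0.093), 14.4-fold, at adjusted p = 3.86e-06. MYCT1, a MYC target gene, rose 13.8-fold from a mean of 5.00 to 8.79. HTN1, which encodes the salivary antimicrobial peptide histatin 1, rose by 3.77 (SE 0.181), 13.6-fold. Its wt-progerin mean of 3.80 lay at percentile 4.57 of the tested genes. CXCL8 went from 5.34 to 8.89, and CCL2, a monocyte chemokine, from 8.53 to 11.38, 7.21-fold. CCL20, a chemokine that binds CCR6, rose 5.50-fold. IL24, a cytokine of the IL-10 family, rose 5.33-fold, from 7.36 to 9.78. The long noncoding RNA UCA1 rose 6.70-fold. TMEM156 rose 6.28-fold. EVI2B, a membrane protein gene of blood cells, rose 5.18-fold from a low mean of 3.96. SLAMF7, a receptor of natural killer and plasma cells, rose 5.16-fold, from 7.14 to 9.51.

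Among the falls, CXCL14 went from 10.98 to 8.43 (SE 0.062, adjusted p = 3.86e-06), 5.85-fold lower. SHOC1, which takes part in meiotic crossing over, fell 4.17-fold, and the long noncoding RNA LUARIS fell 3.97-fold. SDC2, the heparan sulfate proteoglycan syndecan-2, fell 3.28-fold, and TMEM45A fell 3.31-fold. NOX4, an NADPH oxidase that makes hydrogen peroxide, fell by 1.70 on the log2 scale (SE 0.115, adjusted p = 1.10e-04). ACKR3, a scavenging receptor for CXCL12, fell 3.04-fold, as did PIEZO2, a stretch-gated ion channel. AMOT, a binding partner of YAP, fell 3.03-fold. The protease inhibitor A2M fell 2.99-fold, JAKMIP2 2.92-fold, and MN1, a transcriptional coregulator, 2.87-fold. The naming rule required non-overlapping groups for these 24 genes. Each kept its call under every alternative that still tested it, which their choice as the largest changes made likely.

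**Figure D2:**
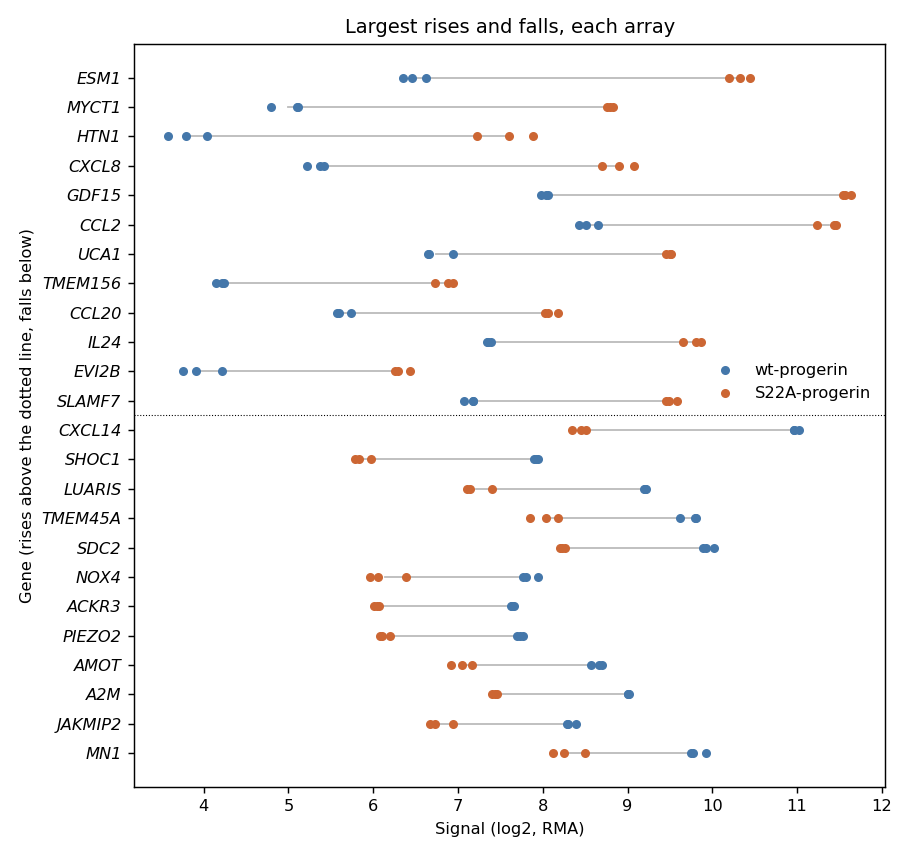
Each row is a gene and each point the log2 signal of an array, blue for wt-progerin and orange for S22A-progerin (n = 3 each), with a line joining the group means. The 12 largest rises are above the dotted line and the 12 largest falls below it, from ESM1 at 3.85 to CXCL14 at -2.55.

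The genes of mitosis and cytokinesis fell as a group (camera adjusted p = 5.52e-31). All 53 measured members fell over all genes tested, and 53 fell when adjusted over the list alone. With the arrays quantile normalized again 51 passed as lower. CDC25C, the phosphatase that activates CDK1 at mitotic entry, fell by 1.05 on the log2 scale (SE 0.058). CENPI, a centromere protein, fell by 0.93, NEK2, a centrosomal kinase, by 0.91, and KIF23, a cytokinesis kinesin, by 0.85. KIF23 was bright in both groups, with means of 11.42 and 10.57. Of 15 genes of chromosome condensation and cohesion, 11 fell, or 12 adjusted over the list alone, and none rose (median -0.32, camera adjusted p = 4.27e-07). The falls included KIF4A (-0.76), a chromosome-bound kinesin, SMC1A (-0.67) of cohesin, SMC2 (-0.58) of condensin and TOP2A (-0.62), DNA topoisomerase II alpha. KIF4A and TOP2A stand in both lists. The members that did not pass were PHF8 (-0.20), STAG2 (-0.11), WAPL (-0.05) and NIPBL (-0.01).

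Genes of DNA replication and the G1/S transition shifted down with a median of -0.42 (camera adjusted p = 6.37e-12), and adjusted p = 0.14 with an estimated correlation. Of 31 measured, 25 fell and 1 rose, against 30 and 1 adjusted over the list alone. With the arrays quantile normalized again 20 fell and 1 rose. Averaging probe sets left 24 falls and 1 rise, as GINS4 (-0.15, adjusted p = 0.305) then did not pass. Without wt-progerin replicate 3, CDT1, DTL, GINS4, MCM7, PCNA, SLBP and TYMS no longer passed. CDC45 (-0.69), GINS1 (-0.55) and GINS2 (-0.59), parts of the replicative helicase, fell, as did E2F8 (-0.80), a repressor of the E2F family. The member that rose was E2F7 (0.24, SE 0.060), also an E2F repressor. CCNE1 (-0.22), CCNE2 (-0.47), CDC25A (-0.18), GINS3 (-0.18) and CDC6 (-0.17) did not pass over all genes. Of 19 genes of homologous recombination and the Fanconi pathway, 13 fell, 15 adjusted over the list alone, and none rose. Their median was -0.43 (camera adjusted p = 7.11e-08; adjusted p = 0.0843 with an estimated correlation). BARD1, the partner of BRCA1, fell by 0.76 on the log2 scale. The helicase gene BRIP1 fell by 0.75 and the nuclease gene MRE11 by 0.54.

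Nuclear lamina and envelope genes, with LMNA left out, shifted down with a median of -0.25 (camera adjusted p = 6.62e-05), and adjusted p = 0.0903 with an estimated correlation. Of 22 measured, 12 fell and 1 rose, against 13 and 1 adjusted over the list alone. Repeated quantile normalization left 11 falls and 2 rises. EMD, LEMD3 and NRM, counted among the falls, no longer passed without wt-progerin replicate 3. LMNB1, lamin B1, fell from 9.83 to 8.94, 1.85-fold, and LMNB2, lamin B2, fell 1.42-fold. TMPO, which encodes the LAP2 proteins, fell 1.87-fold and LBR, the lamin B receptor, 1.70-fold. LPIN1, a phosphatidate phosphatase, rose (0.33, SE 0.063). Of 26 nuclear pore genes, 16 fell, 20 adjusted over the list alone, and none rose, with a median of -0.30 (camera adjusted p = 7.11e-08). Their adjusted p was also 0.0903 with an estimated correlation. Repeated quantile normalization left 14 falls among them, and NUP43 and NUP98 no longer passed without wt-progerin replicate 3. NUP210 (-0.96), a membrane-spanning nucleoporin, moved most, and NUP155 (-0.50), NUP107 (-0.47) and NUP88 (-0.40) fell as well.

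Targets of p53 rose as a group (median 0.62, 1.54-fold, camera adjusted p = 1.41e-13). Of 19 measured, 17 rose and none fell, with 17 and 0 adjusted over the list alone. Averaging probe sets left 16 rises, as FBXO22 (0.08, adjusted p = 0.38) then did not pass. Besides GDF15, the rises included TP53INP1 (0.99), a p53-induced autophagy factor, PMAIP1 (0.85), which encodes the pro-apoptotic protein NOXA, and SESN2 (0.79), a stress-induced inhibitor of mTORC1. SPATA18 (0.14) and PLK2 (-0.04) did not pass. The p53 targets CDKN1A and MDM2 were on the list but were not analysed here, since no probe carried their names.

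NF-kB targets rose as a group (median 0.49, 1.40-fold, camera adjusted p = 5.87e-12). Of 26 measured, 17 rose and none fell, and 20 rose adjusted over the list alone. CXCL8, CCL2 and CCL20 led the list, followed by PTGS2 (1.49, SE 0.082), the inducible cyclooxygenase. Senescence-associated secretory factors, which share 6 measured genes with the NF-kB list, had a median of 0.17 (camera adjusted p = 2.22e-04). The call ended with an estimated correlation (adjusted p = 0.0619) and with the dimmer 50% of genes left out (adjusted p = 0.121). Of 28 measured, 8 rose, 2 fell and 18 did not pass, against 9 and 2 adjusted over the list alone. MMP1, interstitial collagenase, rose 4.01-fold from a mean of 4.91 to 6.91. The falls were TIMP2 (-0.44), an inhibitor of matrix metalloproteinases, and LIF (-0.33), a cytokine of the IL-6 family. IL6, IL1A and IL1B were not analysed here. Among the 8 measured leukocyte markers CD68, a lysosomal membrane protein of macrophages, rose by 1.48 (SE 0.071), while CD14 (0.18), LYZ (0.26) and TYROBP (0.17) did not pass. The leukocyte list counted 1 rise and 0 falls, with 1 and 0 adjusted over the list alone (median 0.12, camera adjusted p = 0.132).

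Interferon-stimulated genes did not pass as a group (median 0.05, camera adjusted p = 0.0891), though they did with the dimmer 50% of genes left out (adjusted p = 0.000722). Of 32 measured, 6 rose, 2 fell and 24 did not pass, with 6 and 2 adjusted over the list alone. RIGI, a cytosolic sensor of viral RNA, rose 2.54-fold, and CXCL10, an interferon-induced chemokine, rose 1.78-fold. SAMD9 (0.56) and TRIM22 (0.48), both antiviral factors, rose as well. IFIT1 (-0.74, SE 0.158) and PLSCR1 (-0.23) fell. Immediate-early and AP-1 genes shifted up (median 0.24, camera adjusted p = 1.15e-04), with adjusted p = 0.234 with an estimated correlation. Of 24 measured, 12 rose and 3 fell, against 15 and 3 adjusted over the list alone. FOSL1 (0.99), an AP-1 subunit, SPRY2 (1.18), a feedback inhibitor of receptor tyrosine kinase signalling, and the transcription factor genes MYC (0.71) and MAFF (0.57) rose. The falls were FOSL2 (-0.42), EGR1 (-0.30) and JUND (-0.25), all transcription factors. JUND did not pass with the arrays quantile normalized again (adjusted p = 0.0567), nor EGR1 with its probe sets averaged (-0.04, adjusted p = 0.746). FOSB, counted among the rises, also missed with its probe sets averaged (0.18, adjusted p = 0.103), which left 11 rises and 2 falls.

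Lysosome and autophagy genes shifted up (median 0.16, camera adjusted p = 2.49e-04), with adjusted p = 0.0903 with an estimated correlation. Of 19 measured, 9 rose and 1 fell, against 11 and 1 adjusted over the list alone. SQSTM1 (0.61), an autophagy receptor, the protease genes CTSB (0.47) and TPP1 (0.55), and NEU1 (0.51), a sialidase, rose. LAMP2 (-0.31), a lysosomal membrane protein, fell, but did not pass with the arrays quantile normalized again (adjusted p = 0.0772) or when any 1 of 5 arrays was left out. Extracellular matrix genes shifted down (median -0.15, camera adjusted p = 0.00425), with adjusted p = 0.0903 with an estimated correlation. Of 15 measured, 6 fell and none rose, against 7 adjusted over the list alone. LUM, the collagen-binding proteoglycan lumican, fell 2.20-fold. FBN1, fibrillin-1 of microfibrils, fell 1.71-fold, and FN1, fibronectin, and EFEMP1, a fibulin, each fell 1.34-fold.

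**Figure D3:**
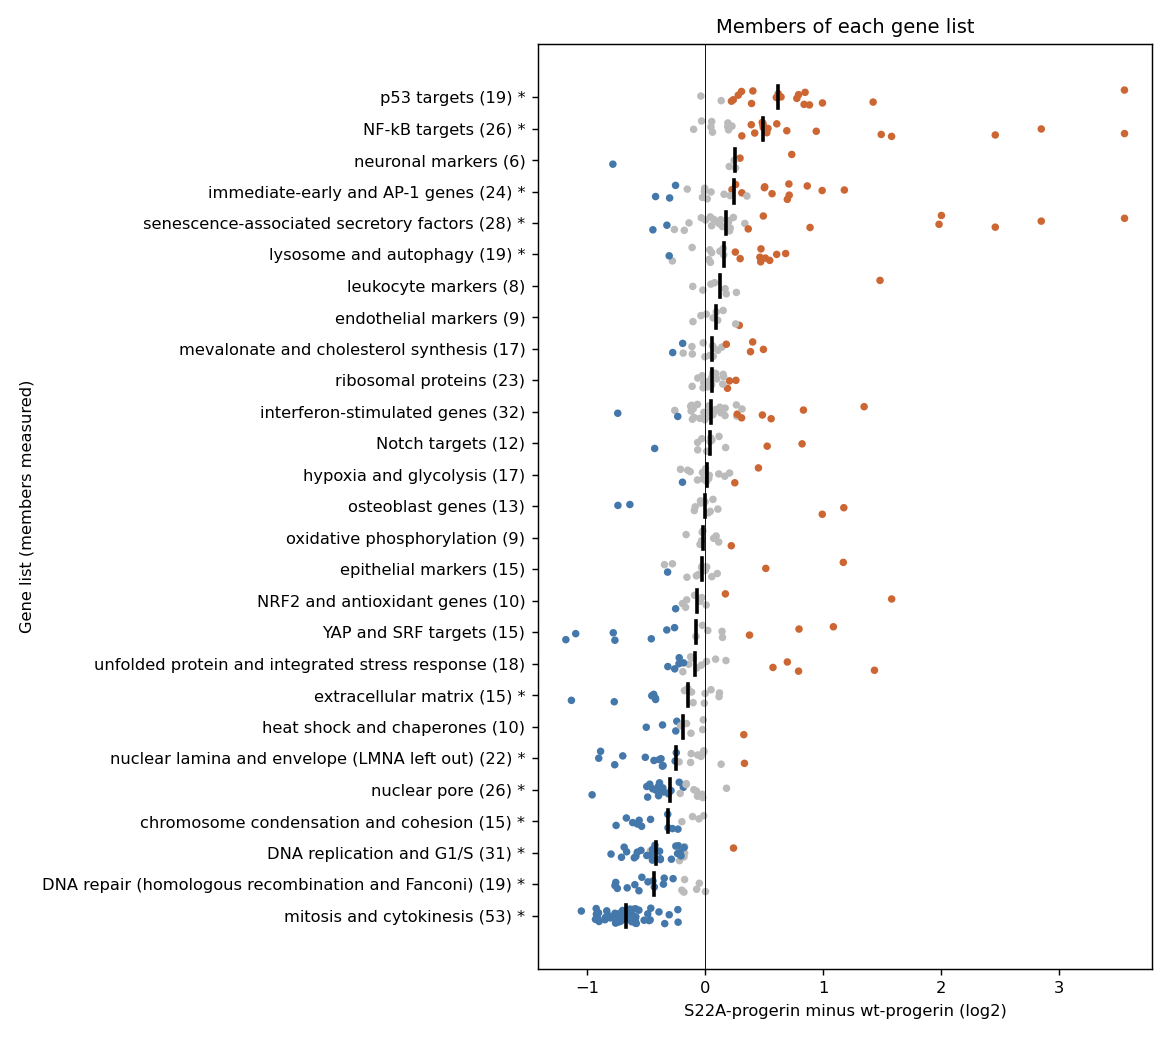
Each row is a gene list with the number of members measured, and each point a member's difference in log2, S22A-progerin minus wt-progerin. Orange and blue points passed the test as higher and lower, grey points did not, bars mark medians and stars mark lists past camera, from p53 targets at 0.62 to mitosis and cytokinesis at -0.68.

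The other lists did not pass camera, and several held members that moved in opposite directions. Of 15 targets of YAP and SRF, 3 rose and 7 fell, against 4 and 7 adjusted over the list alone (median -0.08, camera adjusted p = 0.263). The cytoskeletal genes TPM1 (-1.18) and TAGLN (-1.10) fell, while ANKRD1 (1.09), a cardiac ankyrin repeat protein, and CCN2 (0.79), connective tissue growth factor, rose. The other member that rose was CRIM1 (0.38). Of 13 osteoblast genes, 2 rose and 2 fell, as they did adjusted over the list alone (median -0.00222, camera adjusted p = 0.868). BMP2 (0.99), a bone morphogenetic protein, and SPP1 (1.18), osteopontin, rose. BMP4 (-0.64) and RUNX2 (-0.74), the osteoblast transcription factor, fell. Of 18 genes of the unfolded protein and integrated stress response, 4 rose and 5 fell, against 5 and 6 adjusted over the list alone (median -0.09, camera adjusted p = 0.92). DDIT3 (1.44), which encodes CHOP, ATF3 (0.70), TRIB3 (0.57) and SESN2 rose. The falls were the chaperone gene HYOU1 (-0.32), PSAT1 (-0.26) and PHGDH (-0.18) of serine synthesis, the transcription factor gene XBP1 (-0.22) and the lipoprotein receptor gene VLDLR (-0.22). PHGDH and XBP1 did not pass with the arrays quantile normalized again (adjusted p = 0.132 and 0.0838).

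Of 10 NRF2 and antioxidant genes, 2 rose and 1 fell, against 2 and 3 adjusted over the list alone (median -0.07, camera adjusted p = 0.737). HMOX1, heme oxygenase 1, rose 2.99-fold, TXN (0.17), thioredoxin, rose, and GSR (-0.25), glutathione reductase, fell. GSR did not pass with the arrays quantile normalized again (adjusted p = 0.0975). Of 10 heat shock and chaperone genes, 1 rose and 4 fell, against 1 and 5 adjusted over the list alone (median -0.19, camera adjusted p = 0.0537). BAG3 (0.33), a co-chaperone, rose. HSPA1L (-0.50), CHORDC1 (-0.36), HSPA1A (-0.25) and HSPA1B (-0.24) fell, and HSPA1A and HSPA1B are near-identical copies whose probes may share signal. Of 17 mevalonate and cholesterol genes, 4 rose and 2 fell, against 4 and 3 adjusted over the list alone (median 0.06, camera adjusted p = 0.308). HMGCS1 (0.49), MSMO1 (0.40) and NSDHL (0.18), enzymes of the pathway, and INSIG1 (0.38), a sterol-regulated brake on it, rose. STARD4 (-0.28), a sterol carrier, and FDPS (-0.19), farnesyl diphosphate synthase, fell. With any single array left out, STARD4 was the 1 member that fell.

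Of 12 Notch genes, 2 rose and 1 fell, as they did adjusted over the list alone (median 0.04, camera adjusted p = 0.259). HEY1 (0.82), a Notch-induced repressor, and JAG1 (0.53), a Notch ligand, rose, and NOTCH3 (-0.43), a receptor, fell. Of 17 hypoxia and glycolysis genes, HK2 (0.45), hexokinase 2, and ADM (0.25), adrenomedullin, rose and PGAM1 (-0.19), a glycolytic enzyme, fell, against 1 and 0 adjusted over the list alone (median 0.01, camera adjusted p = 0.655). Of 23 ribosomal protein genes, RPS19 (0.26), RPL19 (0.21) and RPL10A (0.19) rose and none fell, against 2 and 0 adjusted over the list alone (median 0.06, camera adjusted p = 0.06). Of 9 genes of oxidative phosphorylation, COX4I1 (0.22), a subunit of cytochrome c oxidase, rose and none fell, with 1 and 0 adjusted over the list alone (median -0.02, camera adjusted p = 0.655). With the arrays quantile normalized again, ADM (adjusted p = 0.0551), PGAM1 (0.185) and RPL19 (0.0956) did not pass, and RPL19 also missed with its probe sets averaged (0.137).

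Markers of other tissues gave no group shift past the threshold. Of 15 epithelial markers, the keratins KRT15 (1.17) and KRT18 (0.51) rose and KRT14 (-0.32) fell, with 2 and 1 adjusted over the list alone (median -0.03, camera adjusted p = 0.905). Of 9 endothelial markers, CLDN5 (0.29), a tight junction protein, rose and none fell, with 1 and 0 adjusted over the list alone (median 0.09, camera adjusted p = 0.181). Of 6 neuronal markers, STMN2 (0.73) and GAP43 (0.29), growth cone proteins, rose and MAP2 (-0.78), a microtubule-associated protein, fell, against 5 and 1 adjusted over the list alone (median 0.25, camera adjusted p = 0.132).

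Of the 27 lists tested, 5 were called higher, 7 lower and 15 were not called. With an estimated correlation 4 calls held: mitosis and cytokinesis, chromosome condensation and cohesion, p53 targets and NF-kB targets, each at adjusted p = 0.045. Median, mean and test differed in sign in 5 lists, none of them called. For osteoblast, oxidative phosphorylation and epithelial genes the median was negative while the mean and both tests pointed up. In the stress response and NRF2 lists the median and camera pointed down while the mean and the rotation test fry pointed up.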

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

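The tests of vector RNA, leukocyte RNA and an interferon response were chosen after the results were seen. The tests of other splits of the arrays and of a background shift were chosen before. Bootstrap intervals in this part resample the genes of a list or tertile, not the arrays. They treat those genes as independent and do not measure the spread between cultures.

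Probe sets with no gene name here gave a signal outside the comparisons of named genes. They were tested in a limma fit adjusted over all 53617 probe sets, of which 5361 passed. Of 37519 such probe sets, 2925 (7.8%) passed between the groups, 1498 higher and 1427 lower in S22A-progerin. The share of named genes that passed comes from another adjustment and cannot be set beside it.

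The number of changed genes was set against the other ways of parting the 6 arrays into 3 and 3. The real split gave 3777 genes and the highest of the others gave 0 by limma, with 282 to 435 genes at an unadjusted p under 0.05 there against 5463 in the real split. Each other split mixes arrays of both groups, so the group difference widens the spread within each side and holds the count down. The contrast with 0 therefore says little. Only 1 of the 10 splits reached the real count, and 10 splits are too few for a share under 0.05. More vector RNA in the S22A-progerin cells may account for part of the difference. The LMNA difference of 0.146 did not pass (limma adjusted p = 0.0796), but its 95% interval of 0.026 to 0.266, not adjusted over genes, lay above 0. It therefore neither established nor excluded more vector RNA. The probe set was taken to read vector and cellular transcripts together, so its value was not split between them. The S22A change itself stays open as the biological explanation.

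The rise of NF-kB targets and secretory factors was weighed against RNA from other cells and against a response to the virus. The leukocyte markers had a median of 0.124 (bootstrap 95% interval -0.02 to 0.264) against 0.606 for the 21 genes that rose. This cannot decide on leukocyte RNA, because those genes were picked for having risen and 4 of the 8 markers lie in the dimmest tertile. The labels name only U-2 OS cells and no source of leukocytes. CD68, which other cells also express, rose with all arrays in the fit, 2 markers rose without wt-progerin replicate 1 or S22A-progerin replicate 3, and the list rose by fry (adjusted p = 0.00122). The median of the interferon list minus that of the NF-kB list was -0.438 (bootstrap 95% interval -0.545 to -0.169), and -0.386 (-0.744 to -0.148) without the dimmest tertile, but -0.268 (-0.529 to 0.002) without the dimmer 50% of genes, so a general interferon response of the size of the NF-kB shift stays open. That S22A-progerin raises these genes is a hypothesis left open, and a difference in infection or selection between the cultures could do the same.

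Rises outnumbered falls among genes of low level, and a background difference between the arrays could have lifted that whole tertile. All its genes together had a median of 0.0289 (bootstrap 95% interval 0.0241 to 0.0347), against 0.416 for the 333 genes that rose there. This comparison decides nothing, because the latter were picked for having risen and quantile normalization removes most of a shift that all dim genes share, so a background difference stays open. No biological explanation for the imbalance was tested.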

How the results depend on the processing

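The counts of list members without each array and the calls of members outside the rule were chosen after the data were seen, and all other alternatives in this part were planned. No called result reversed its direction. Among 124 genes named by the rule, at most 11 lost their call in another fit (without wt-progerin replicate 1), while 13 did at an adjusted p under 0.01 and 71 at a fold of at least 2. None of the 24 with the largest changes lost theirs in any of these. Those 24 were picked for the size of their change in these same arrays, so this says little about how firm they are. Without single arrays the calls lost were those of PGAM1, GSR, RPL10A, TXN, ADM, CHORDC1, KRT14, COX4I1, GAP43, RPL19 and RPS19. Of the members named outside the rule, E2F7, LIF, PLSCR1, EGR1, JUND, PHGDH, XBP1, VLDLR, HSPA1B, NSDHL, FDPS and LAMP2 lost theirs in at least 1 of those fits. So did AURKA, BUB3, CENPN, AEN, APAF1, FBXO22, CDT1, DTL, GINS4, MCM7, PCNA, SLBP, TYMS, EMD, LEMD3, NRM, NUP43, NUP98 and FOSB. LMNA passed with quantile normalization again, at 0.177 (adjusted p = 0.0356), for a cause not tested, and at 0.146 with the dimmest tertile (adjusted p = 0.0374) or the dimmer 50% of genes (0.0237) left out, where fewer genes are adjusted for. The interferon list passed with those genes left out, at 0.018 and 0.000722, and with fry, at 0.00255, over a range of 0.000722 to 0.238. The filters removed members, and fry does not compare with other genes. The secretory list missed at 0.121 with the dimmer 50% left out, which leaves 10 of its 28 members and removes CCL20 and MMP1. With an estimated correlation 4 of 27 lists were called, and the secretory, replication and lamina lists missed at 0.0619, 0.14 and 0.0903. Testing all 53617 probe sets gave 5361 that passed, 2505 higher and 2856 lower. A fold of at least 2 left 228 genes (152 higher, 76 lower), and an adjusted p under 0.01 left 2078 (852 and 1226). Without single arrays, 2647 to 3601 genes passed (1126 to 1553 higher, 1514 to 2048 lower), 12 to 13 lists were called and LMNA lay at 0.126 to 0.161. Small counts moved with fewer arrays: falls in the stress response list were 2 to 4, not 5, falls among heat shock genes 2 to 4, falls among immediate-early genes 1 to 3, falls of secretory and interferon genes 1 to 2, the rise of E2F7 and the fall of LAMP2 0 to 1, and rises among ribosomal genes 0 to 4. Falls in the mevalonate list were 1, not 2, with any single array left out, and the small counts of the hypoxia, NRF2, oxidative phosphorylation, leukocyte, epithelial and neuronal lists moved by up to 1. The ribosomal list passed in 8 of 18 alternatives (0.00583 to 0.234) and the heat shock list in 4 of 18 (0.000797 to 0.234). No pairing by replicate number was visible, since deviations of same-numbered arrays correlated at -0.019, -0.055 and -0.006. These values cannot tell whether same-numbered cultures were handled together. The fit with a replicate block called 2990 genes, against 3777 without it. Signal over background is not known here, which limits all statements on dim genes.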

Other observations

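The test of symbol families and the test of neighbouring genes were chosen before their results were seen. The microRNA genes and the members of families named here were picked after their values were seen, and the families were set against other scalings after their results were seen.

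Some families of genes with a shared symbol start shifted beyond the fixed lists. No call of a family held with an estimated correlation (adjusted p = 0.867 for each). Each median kept its sign with the arrays quantile normalized again or centred on their medians. Centring could not have turned a sign, because it moves all genes alike and by less than any of these medians. Of 38 tested genes whose symbols start with CEP, mostly centrosomal proteins, 19 fell and 2 rose (median -0.31, camera adjusted p = 7.37e-05 over 179 families). CEP70 fell by 1.04 on the log2 scale (SE 0.052) and CEP152, a scaffold of centriole duplication, by 0.75, while CEP85L (0.90) and the pseudogene CEP192P1 (0.32) rose. Of 17 IFT genes, which carry cargo along cilia, 9 fell and 1 rose (median -0.19, camera adjusted p = 0.039), among them IFT122 (-0.54) and IFT70A (-0.51), with IFT20 (0.35) the rise. The 41 CFAP genes, also of cilia and flagella, did not pass as a family (median 0.002, 4 higher and 2 lower, camera adjusted p = 0.862). Of 19 protocadherin beta genes and pseudogenes, 12 fell and none rose (median -0.37, camera adjusted p = 0.00998), with PCDHB5 at -0.93. Late cornified envelope genes, which are epidermal, went the other way. Of 17 measured, 5 rose and none fell (median 0.19, camera adjusted p = 0.0277). LCE1B went from 3.44 to 4.95 and LCE1F from 5.02 to 6.83, and LCE2D (0.44), LCE3C (0.42) and LCE3D (0.36) also rose. The protocadherin beta and late cornified envelope genes are similar copies within a cluster, so values of single members are uncertain.

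Of 11 genes whose symbols start with TLR, which are Toll-like receptors and the antisense RNA TLR8-AS1, 4 rose and none fell (median 0.25, camera adjusted p = 0.0433, and adjusted p = 0.867 with an estimated correlation). TLR4, the receptor for bacterial lipopolysaccharide, rose 2.55-fold from a mean of 8.80, TLR1 rose by 0.65, TLR3 by 0.60 and TLR6 by 0.30. The microRNA genes MIR146A, an NF-kB target, and MIR221 rose by 2.35 (SE 0.069) and 1.59 (SE 0.084), and MIR222 by 1.35 (SE 0.316). A whole-transcript protocol reads mainly precursors or host transcripts of such genes. Of 1072 microRNA genes, 43 rose and 38 fell.

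Whether families with a shared symbol start shift together was tested on 179 families of at least 10 genes. Of the 10 that passed camera, 8 lay mostly outside the fixed lists. Besides those described, these were KIF, the kinesins, with 19 lower and 2 higher of 40, 11 of which are in the fixed lists (median -0.22, camera adjusted p = 0.000338), CD with 15 higher and 4 lower of 73 (median 0.09, camera adjusted p = 0.0377) and IL with 12 higher and 3 lower of 55 (median 0.07, camera adjusted p = 0.039). Those 11 kinesins stand in the mitosis list, whose measured members all fell. They make up 11 of the 19 KIF falls, so the KIF shift largely repeats that list. The CD and IL symbols cover many leukocyte genes. The marker values did not decide on leukocyte RNA as a source, and the labels name only U-2 OS cells. None of the 10 passed with an estimated correlation (adjusted p = 0.867 for each).

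Whether neighbouring genes change together was tested on 10085 pairs of non-overlapping protein-coding genes of different families. The genes of a pair are adjacent in the order of tested genes, and untested genes may lie between them. Their differences correlated at r = 0.063 across genes (Spearman 0.063), where 10000 shuffled orders gave -0.018 to 0.023. The permutation p of 1e-04 is the smallest those shuffles can give. Genes 2, 5, 10 and 20 places apart in that order correlated at 0.021, 0.018, 0.016 and 0.024. A weak response shared by nearby tested genes may therefore be present, but the correlation of 0.063 is small. Shared promoters were not tested apart from larger domains, and a shared expression level was not tested as a source.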
